A study of Mus musculus with 2 samples.

How the data were processed

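EBF1 ChIP-seq and input DNA of the 38B9 cell line were analysed from the aligned reads and the peak list the authors deposited. Per the labels, cells were fixed with formaldehyde and chromatin was sheared by sonication. Linkers were added to equal amounts of ChIP and input DNA, and fragments were amplified by PCR and selected by size on a gel. Reads were placed on mouse build mm8, per the submitters' processing notes, and the aligner and its settings are not given in the sources used here. Each read carries an alignment score that the authors deposited with it, and this score was not used to filter reads. Per the text deposited with the peak list, the authors called enriched regions in the ChIP sample with CCAT. The threshold of the call is not given in the sources used here.

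The deposited tag counts of a peak are whole-number counts of ChIP and control reads. The deposited fold of each peak is, per the same text, not the ratio of these counts, since it holds a term for low control counts. Tested on the list, the authors' fold had a denominator of 8.20 at 6920 peaks (72.4%, tolerance 0.01) and never less, whatever the control count. The deposited tag counts ran from 19 to 405 with a median of 27, and the deposited fold from 2.21 to 31.2 with a median of 3.05. Of the settings tried on the reads, 1 read per position and strand, a shift of 100 bp and a window of 300 bp came closest to the authors' counts, with 67.5% of the ChIP counts equal and 93.2% within 1. The fold served only to rank and filter peaks.

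Each read was counted once per position and strand within a library and placed at its 5' end shifted by 57 bp. This moves it to the middle of a fragment of 114 bp, a length estimated from the distance between strands in peaks. Duplicate reads were few, since 97.2% of the EBF1 reads and 97.0% of the input reads were distinct. Reads in a peak were summed over lanes, because the lanes are repeat runs of a library and not replicates. The ChIP and input counts of each peak were compared by a two-sided exact binomial test against the share of ChIP reads in both totals (ratio of totals 1.00), with Benjamini-Hochberg adjustment at 0.05. Ratios of RPM (reads scaled to the distinct reads of the library) carry exact conditional (Clopper-Pearson) intervals at 95%, and shares carry exact binomial ones. Amplified reads without molecular identifiers are not independent molecules, so intervals cover counting error only. A peak of median depth, with 35 ChIP and 12 input reads, is therefore known only roughly. In simulated data drawn for 9561 peaks, with 200 of them raised, the test called 5% of peaks raised 2-fold, 48.5% of those raised 3-fold and 93.5% of those raised 5-fold, with 0, 1 and 11 unchanged peaks called. With few peaks raised the adjustment is stricter than in the list itself, so these shares are not the detection limits of the list. The intervals held the true ratio in 96.6 to 97.0% of peaks.

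No genome of build mm8 was used. Sequence was rebuilt on the forward strand from reads without mismatches (86.2 to 87.5% of reads per lane), which covered 37.7% of the length reached. Bases covered on both strands were the same in 100% of 215154683 positions. Reads without mismatches repeat the reference bases they were placed on, so this agreement checks only their placing and strand. The rebuilt sequence is in effect that of the reference and not of the cell line. Uncovered bases matched nothing. Windows reached 100 bp to either side of a peak centre. Each peak was paired with a control region of the same width centred on a random input read on the same chromosome outside peaks, and both were searched only where both were covered. An alternative set of control regions was matched on GC content in steps of 2 percentage points from 10 candidate regions per peak, which found a match for 9535 peaks. Shares were compared by two-sided Fisher's exact tests with the sample odds ratio and its Woolf interval, and p-values below 1e-300 were written as 1e-300. In a test on simulated data, 51.5% of 200 sites planted in 4000 random windows were found, and 100% of those where at least 90% of the window was covered. None of 6 site forms passed without planting, and a planted word ranked 1 of all words. Groups of peaks by strength came from ChIP minus input RPM, with a Spearman correlation and 100000 permutations.

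Windows of 500 bp across the genome were called with at least 20 ChIP reads, a ratio of at least 5 and an adjusted p of 0.001 or less. Input depth was the median of 1 Mb bins per chromosome relative to the autosomes, with a lowess fit (span 0.3) against GC content for the corrected values and 2000 bootstrap draws of bins for their intervals. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

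The tests, the 14 motifs, the rule for named peaks and most alternatives were fixed before the data were examined. The rule named the 10 peaks with the most ChIP minus input RPM. The alternatives were all reads in place of distinct reads, the peaks with the highest deposited fold, scaling by 10 kb bins outside peaks, 200 bp around the centre, each lane alone, other windows and ratios, other search widths, 1 mismatch, control regions 2 kb to a side or matched on GC content, and smaller bins for input depth. Added after the data were seen were the limits to well covered windows, 1 peak per distinct region, GC-matched control regions for the spacer forms, the joining of central dinucleotides over both strands and the GC correction of input depth. The position of peaks relative to genes, the nearest gene of each named peak, a fixed set of named genes and 11 fixed gene lists were not analysed here. They need gene positions in mm8, and the gene table at hand, of assembly GRCm38.p6, served for none, since coordinates were not converted between builds.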

Results

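EBF1, a transcription factor required for the B cell lineage, was mapped on chromatin of 38B9 cells, a mouse pre-B cell line transformed by the Abelson leukemia virus. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) gave 1 EBF1 library, made with a rabbit polyclonal antibody against EBF1, and 1 input library of sheared DNA that was not precipitated. Each library was run on 2 lanes of a flow cell. The EBF1 lanes held 13472117 and 13313904 aligned reads of 35 bases, and the input lanes held 13222728 and 13578333. With lanes joined and 1 read kept per position and strand, 26040227 EBF1 reads and 25991055 input reads remained. There was 1 library per group, so every test on reads compared these libraries and not conditions, no difference had a replicate check, and every interval covers counting error only. Regions are named by their position in mouse genome build mm8, and gene annotation of that build was not used here.

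The first comparison set ChIP against input reads at each region the authors had called as enriched. The authors listed 9561 peaks, and 8591 of them (89.9%) held more EBF1 ChIP than input reads, none held fewer, and 970 did not pass the test. The median peak held 35 ChIP reads and 12 input reads. The median ratio of ChIP to input was 2.99, with quartiles of 2.39 and 4.16. The ratio was at least 5 at 1467 peaks and below 2 at 921 peaks, and 6 peaks had no input read. The test was a two-sided exact binomial test per peak with Benjamini-Hochberg adjustment at 0.05. The peaks had been called from the same reads, so the count largely restates that call and is no independent evidence of it. Of the 9561 peaks, 421 shared their region with another listed peak, and with 1 peak kept per distinct region 8374 of 9344 regions passed. With the first lane of each library alone 5501 peaks passed, and with the second lane alone 5993.

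The region with the largest excess of ChIP over input reads lay on chromosome 18, from 10918050 to 10918990. It held 455 ChIP reads against 26 input reads, a ratio of 17.5 (95% interval 11.8 to 27.0, exact binomial test, adjusted p = 2.39e-98). TCCCAGGGGA, an exact match to the textbook EBF site TCCCNNGGGA, lay at 10918552 to 10918561 in the forward-strand context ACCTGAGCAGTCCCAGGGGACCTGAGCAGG. Around it were 5 copies of TCTCAGGGGA, each with 1 mismatch to the site, starting at 10918450, 10918491, 10918533, 10918590 and 10918631. The copy at 10918491 read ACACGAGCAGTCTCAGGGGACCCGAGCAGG with its flanks, and GAGCAG lay in the flanks of each copy of this array.

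The next region lay on chromosome 17, from 27426910 to 27428020, with 340 ChIP and 28 input reads, a ratio of 12.1 (8.24 to 18.5, exact binomial test, adjusted p = 9.62e-66). It also held an array of sites, with 4 exact matches and 4 sites with 1 mismatch within 250 bp of its centre. The exact matches were TCCCCTGGGA at 27427288 and 27427321, TCCCTTGGGA at 27427389 and TCCCATGGGA at 27427554. The first of these read GGCTCACAGTTCCCCTGGGAGGAGAGGTCA with its flanks, and the third read GGCTCACAGTTCCCTTGGGAGGAGAGGTCA.

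**Figure D1:**
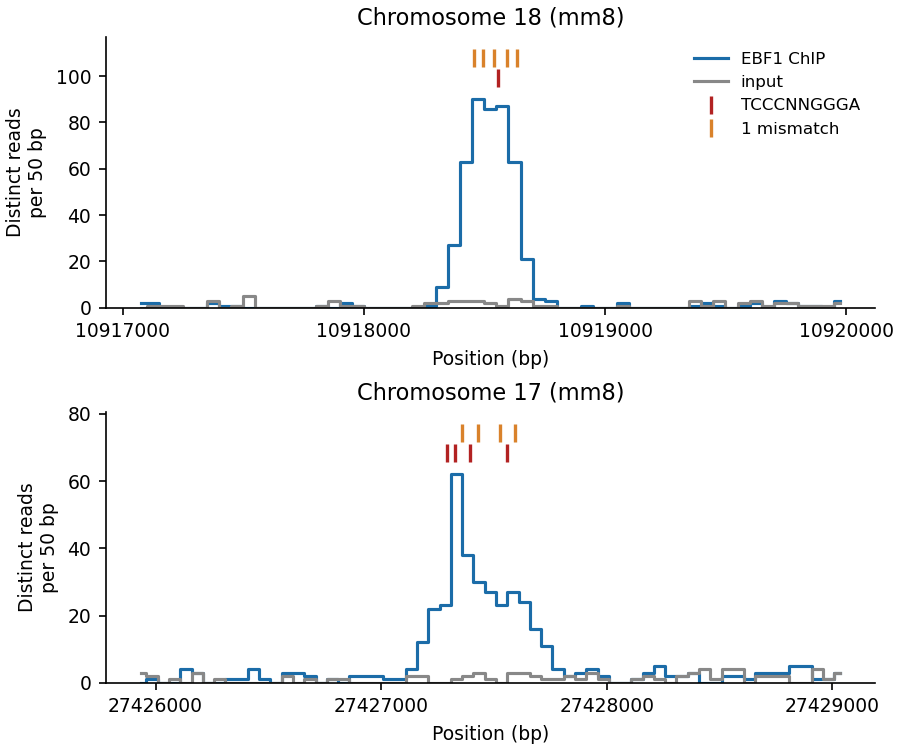
Distinct reads per 50 bp (vertical axis) along the strongest EBF1 region on chromosome 18 and the next on chromosome 17 (horizontal axes, mm8 position in bp), with the EBF1 ChIP library in blue and input in grey. Red ticks mark exact TCCCNNGGGA sites and orange ticks sites with 1 mismatch, and ChIP reads rise over the site arrays while input reads stay near the base line.

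On chromosome 7, the region from 81982510 to 81983410 held 292 ChIP reads and 12 input reads, the highest ratio among the 10 strongest peaks at 24.3 (13.7 to 47.5). It had no exact site within 250 bp of its centre, and a TCCCCAGAGA with 1 mismatch began at 81982751, at a distance of -169 bp from the centre. Chromosome 8 held 3 of these regions. The span from 74525640 to 74527160, listed as a pair of peaks, had 302 ChIP and 40 input reads (ratio 7.54, 5.41 to 10.8). Reads were counted over whole spans, so each peak of a pair takes the reads of both. The deposited tag counts of this pair were 196 and 36. TCCCCTGGGG, with 1 mismatch, began there at 74526552, at -48 bp from the peak centre at 74526605. The region from 124326010 to 124327030 had 274 and 28 reads (ratio 9.77, 6.61 to 15.0) and an exact TCCCTTGGGA at 124326595. The region from 109226810 to 109227800 had 263 and 20 reads (ratio 13.1, 8.33 to 21.8) and TCCGTTGGGA, with 1 mismatch, at 109227212. On chromosome 5, the span from 118755620 to 118756910, also a pair of peaks, had 281 and 29 reads (ratio 9.67, 6.59 to 14.7). The deposited tag counts of that pair were 164 and 64. An exact TCCCTGGGGA began there at 118756555, at 175 bp from the peak centre at 118756385. The last of the 10 was 1 of a pair of peaks with equal read counts in a span of chromosome 9 from 103346510 to 103347750. The span had 280 and 40 reads (ratio 6.99, 5.00 to 9.99). Within 250 bp of the centre of the named peak, at 103346885, lay 3 sites with 1 mismatch. Sites around the other peak of the pair were not listed, so this count does not cover the whole span.

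How much of each library fell in the peaks was compared next. The peaks covered 5469424 bp and took 1.57% of the distinct EBF1 ChIP reads (exact binomial 95% interval 1.57 to 1.58%) and 0.468% of the input reads (0.466 to 0.471%), a ratio of 3.35. By lane, the shares were 1.62% and 1.61% for EBF1 and 0.473% and 0.466% for input. For the 4780 peaks with the highest deposited fold the shares were 1.08% and 0.278%. No test was made of these shares.

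The repeat lanes of each library were compared to bound the sequencing part of the error. No peak differed between the EBF1 lanes after adjustment of exact binomial tests by the Benjamini-Hochberg method, and 315 of 9561 had an unadjusted p under 0.05. For the input lanes none differed after adjustment, and 312 had an unadjusted p under 0.05. Across peaks, which are not independent replicates, the lanes of the EBF1 library correlated at Pearson 0.931 and Spearman 0.786. The lanes of the input library, with fewer reads per peak, correlated at 0.584 and 0.483. Lanes shared a DNA preparation, so these values leave out the error of culture, precipitation and library making.

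The sequence under the peaks was searched for the EBF site. TCCCNNGGGA lay within 100 bp of the centre in 13.4% of peaks and 0.241% of control regions placed on random input reads, when both were searched over the same covered positions. The odds ratio was 64.0 (42.3 to 96.7; two-sided Fisher's exact test, p = 1e-300, the smallest value written). Over all positions covered in peaks within 100 bp of the centre, 19.5% held the exact site (18.7 to 20.3%). Among 7542 peaks with at least 90% of the window covered, 20.8% held the exact site (19.9 to 21.8%) and 62.8% held it with at most 1 mismatch (61.7 to 63.9%). More than 1 exact site lay in 38 of these peaks. Sites were concentrated at the centres, at 30.8 per 10000 covered positions in the 20 bp just before the centre, and the median distance of 2074 sites within 250 bp was 19 bp. Of those sites, 53.1% lay within 20 bp and 81.0% within 50 bp. Sequence came from reads without mismatches, which covered a median of 98.5% of the window in peaks and 65.7% in control regions, so the odds ratio was taken only over positions covered in both members of a pair. Allowing 1 mismatch lowered it to 15.6 (14.1 to 17.4), with a site in 41.6% of peaks and 4.36% of control regions over shared positions. Counting sites within 250 bp lowered the odds ratio to 29.1, and counting those within 50 bp raised it to 131.

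**Figure D2:**
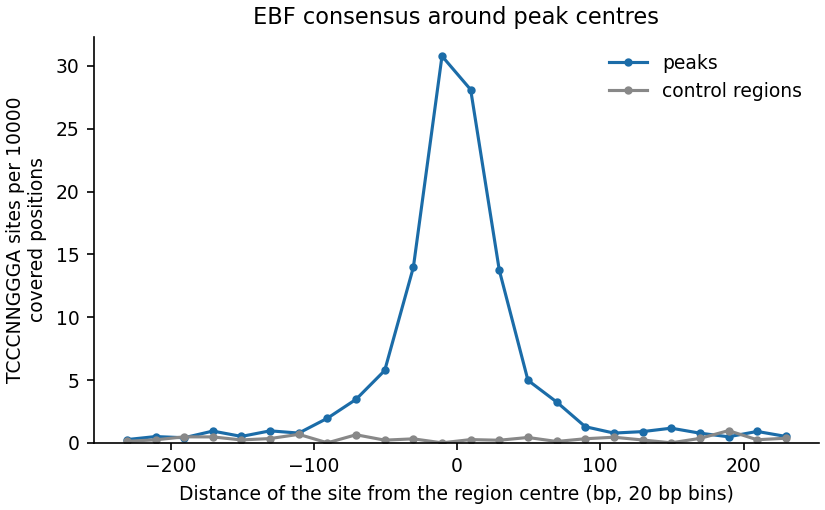
Exact TCCCNNGGGA sites per 10000 covered positions (vertical axis) by distance from the region centre in bins of 20 bp (horizontal axis), for EBF1 peaks in blue and control regions in grey. Peaks reach 30.8 sites at the centre, where control regions stay near 0.

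Stronger peaks more often held the site. Peaks were ranked by ChIP minus input RPM (reads scaled to library size) and split into 5 groups of equal size. RPM was counted over the whole listed region, from 180 to 1950 bp wide, so the rank also depends on width and on peaks that share a region. The site was found in 28.1% of the strongest group (26.1 to 30.2%), then in 23.1%, 21.5% and 15.4%, and in 9.26% of the weakest group (8.00 to 10.6%). Spearman's rho across peaks was 0.169 (permutation test, p = 1e-05, the smallest that 100000 permutations can give), and peaks are not replicates. Among peaks with at least 90% of the window covered the shares ran from 29.8% to 9.88%.

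**Figure D3:**
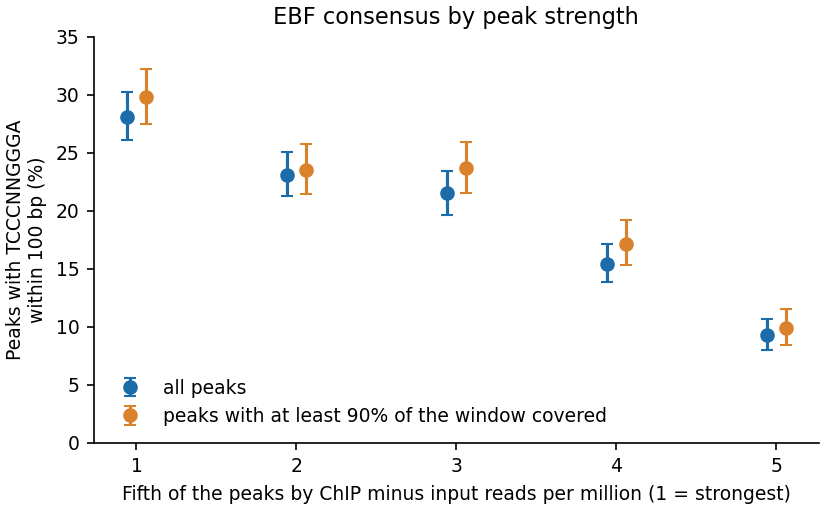
Share of EBF1 peaks with TCCCNNGGGA within 100 bp of the centre, in percent (vertical axis), for 5 groups of peaks from strongest (1) to weakest (5) by ChIP minus input RPM (horizontal axis). Points are shares and bars are exact binomial 95% intervals, and shares fall from 28.1% to 9.26% for all peaks (blue) and from 29.8% to 9.88% for well covered peaks (orange).

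Versions of the palindrome with other spacers and centres were compared. A spacer of 2 bases stood furthest above control regions, at an odds ratio of 64.0. Spacers of 3, 4 and 5 bases were also more frequent in peaks, with TCCCNNNGGGA in 3.31% of peaks and 0.115% of control regions (odds ratio 29.7, 16.3 to 54.2), TCCCNNNNGGGA in 1.18% and 0.157% (7.61, 4.44 to 13.1) and TCCCNNNNNGGGA in 0.387% and 0.136% (2.85, 1.52 to 5.37). TCCCNGGGA, with a spacer of 1 base, was found in 0.397% of peaks and 0.366% of control regions and did not pass the test (odds ratio 1.09, Fisher's exact test, adjusted p = 0.815). All 16 central dinucleotides of the 2-base spacer, read on the forward strand, passed. Read from both strands they make 10 distinct sites. Of these TCCCTGGGGA, which reads TCCCCAGGGA on the other strand, was found in 4.23% of peaks and TCCCAGGGGA, which reads TCCCCTGGGA, in 4.02%. Each was found in 0.0732% of control regions (odds ratios 60.2, 28.5 to 127, and 57.1, 27.0 to 121). TCCCAAGGGA, which reads TCCCTTGGGA, was found in 2.08% against 0.0209% (odds ratio 102, 25.2 to 409). TCCCTAGGGA and TCCCGCGGGA are each their own reverse complement. TCCCTAGGGA was found in 0.795% against 0.0105% (76.6, 10.7 to 551) and TCCCGCGGGA in 0.0732% of peaks. The order by share was thus not the order by odds ratio, and the intervals overlapped. In all, 21 of 22 forms passed two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. Against control regions matched on GC content 19 passed, the 3-base spacer fell to an odds ratio of 10.5 and the 5-base spacer to 1.68. There TCCCGGGA, with no spacer (3.68 against random control regions and 1.40 against matched ones), and TCCCGCGGGA no longer passed, and the 1-base spacer turned to 0.654 (Fisher's exact test, adjusted p = 0.0565).

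Sites of other factors known in early B cells were counted in the same windows, with MYC and GATA sites kept as controls. STAT5 sites were counted only in regions without the exact EBF site (8283 peaks and 9538 random control regions). Peaks held more sites for ETS factors (2.42% of peaks against 0.899% of control regions), RUNX (4.78% against 2.37%), E-box proteins of the E2A type (23.7% against 15.5%) and OCT factors (0.826% against 0.544%). They also held more MYC E-boxes (2.99% against 1.79%), GC boxes bound by SP factors (6.19% against 1.70%) and CTCF cores (2.89% against 1.12%), and fewer GATA sites (0.816% against 1.29%). Of 14 motifs, 7 were more frequent and 1 less frequent in peaks after Benjamini-Hochberg adjustment of two-sided Fisher's exact tests. IKAROS, NFY, PAX5-like, FOXO, STAT5 and NF-kB sites did not pass. PAX5-like sites were found in only 12 peaks and 6 control regions (odds ratio 2.00, 0.751 to 5.33). NF-kB sites were found in 4 and 1 (4.00, 0.447 to 35.8). These 2 were too rare for the test to tell.

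Peaks were richer in GC (median 53.9%) than random control regions (46.8%), and control regions matched on GC content changed part of this picture. RUNX (odds ratio 2.77, 2.35 to 3.27), OCT (2.60, 1.75 to 3.87) and ETS (2.36, 1.91 to 2.93) stood furthest above the matched regions. SP fell from an odds ratio of 3.81 to 1.33, E-boxes from 1.69 to 1.16 and MYC E-boxes from 1.69 to 1.32, and all still passed. MYC sites had been kept as a control, so gains of this size cannot be taken as particular to factors of early B cells. CTCF cores (1.19, adjusted p = 0.0723) and GATA sites (0.892, adjusted p = 0.534) no longer passed Fisher's exact test. FOXO sites turned from an odds ratio of 0.866 that did not pass to 1.46, which did (1.12 to 1.90, Fisher's exact test, adjusted p = 0.0110). In a search of 32827 words of 8 bases, 2415 were more and 3259 less frequent in peaks, and CCCCAGGG (12.8% against 0.690%) and CCCAGGGG (11.1% against 0.533%), which overlap versions of the EBF site, led the list. Against matched control regions 478 words were more and 247 less frequent, with the same pair in the lead.

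**Figure D4:**
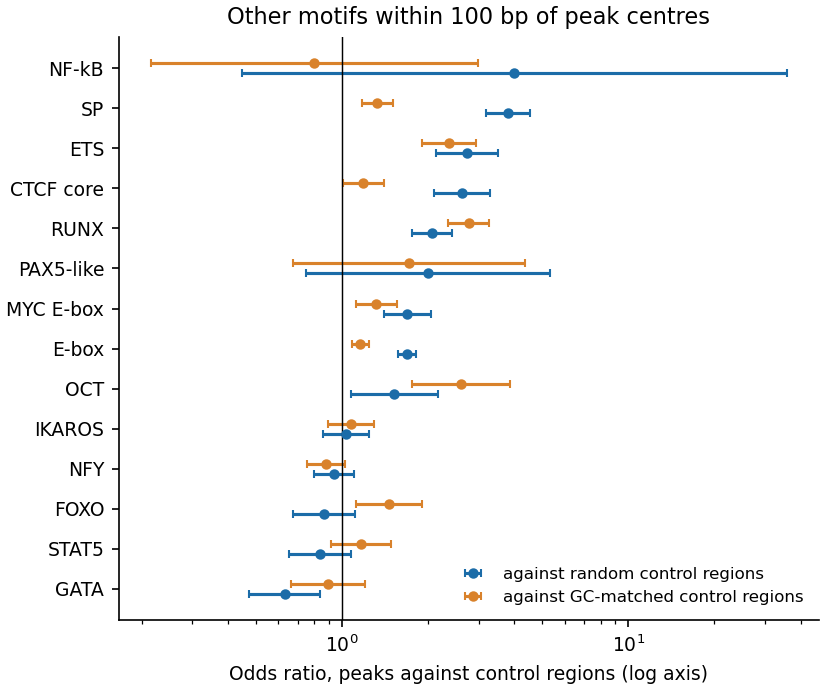
Odds ratio of each motif in EBF1 peaks against control regions (horizontal log axis), with random control regions in blue and GC-matched ones in orange. Points are odds ratios and bars are 95% intervals; RUNX, OCT and ETS lie furthest above 1 against GC-matched regions at 2.77, 2.60 and 2.36.

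The genome was then scanned for enriched regions without reference to the peak list. Of 48353 windows of 500 bp with at least 20 ChIP reads, 1934 had a ratio of at least 5 and passed the exact binomial test at an adjusted 0.001. Of these, 1895 touched a listed peak and 39 did not. The outside window with the most ChIP reads lay on chromosome 8 from 122321501 to 122322000, with 49 ChIP and 9 input reads (ratio 5.43, 2.64 to 12.6). With the libraries exchanged, 3 windows passed. All reads in place of distinct reads gave 95 outside windows, and a ratio of at least 10 left 21. The windows touched 1952 of the listed peaks, or 20.4% (19.6 to 21.2%), and 37.4% of the 4780 peaks with the highest deposited fold. The rule asked for a ratio of at least 5, and 1467 of the 9561 peaks reached that over their whole region. A low share thus largely reflects the rule. The scan used the same reads as the peak list and is no independent evidence for it.

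Input depth per chromosome was measured as a view of copy number in the line. Chromosome X lay lowest, at 0.329 of the autosomal median per 1 Mb bin, and chromosome 11 highest, at 1.31. Chromosomes 9 (1.12) and 17 (1.11) also lay more than 10% above the median, and chromosomes 3 (0.845), 14 (0.888) and 16 more than 10% below it. Input reads rose with GC content across 2393 autosomal bins (Spearman 0.899), and after correction for GC only chromosome X differed by more than 10%, at 0.445 (bootstrap 95% interval 0.431 to 0.472). No test was made of these depths, GC content was taken from covered bases alone, and the 10% rule was chosen after the values were seen.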

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

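The windows outside the peak list came from a planned scan. The search for sites in them, and all tests of explanations given here, were chosen after the patterns were seen. What each explanation predicted was written before its test was run, with later changes to a window and to rules named beside them.

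Outside the authors' peaks, 39 windows of 500 bp held more ChIP than input reads, in regions the list leaves out of the same libraries, against 3 when the libraries were exchanged. Of these 39 windows, 11 held an exact EBF site (28.2%, 15.0 to 44.9%) against 0.743% of control regions of that width (odds ratio 52.5, 25.2 to 110, two-sided Fisher's exact test, p = 1.22e-14). With at most 1 mismatch, 25 windows (64.1%) held a site against 1049 of 9561 control regions. The windows were better covered with sequence (median 76.6%) than the control regions (57.7%), and this comparison was not limited to shared positions.

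The excess of ChIP reads in peaks was weighed against GC content, since peaks are richer in GC than random regions. A ChIP library that favours GC-rich DNA would give the same excess at regions outside peaks of equal GC content. There the pooled ratio over the 100 bp to either side of the centre, without the input read each region was centred on, was 1.09 (95% interval 1.08 to 1.11), against 5.85 in the peaks, which argues against GC content as the source of more than a small part. The peaks had been called on excess in these reads and the matched regions lay outside them, so the gap is partly set by that choice. The first count used only the flanks of those regions and gave an interval of 1.04 to 1.07, and the window was changed after that value was seen. Other properties of an antibody, such as binding to open chromatin or to another protein, were not tested, and no biological explanation could be tested with 1 library of each kind.

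Chromosomes 11 and X stood apart in input depth, and chromosome X held 49 peaks, 0.302 per Mb. After correction for GC content chromosome 11 lay at 1.01 (0.995 to 1.03), so GC content may account for its high depth, while chromosome X stayed at 0.445 (0.431 to 0.472), which GC content does not account for. That interval lies below 0.5, the depth of a single copy, but the intervals of chromosomes 7 (0.904 to 0.957) and 16 (1.04 to 1.09) also miss 1, so the number of X copies was left open. If lower depth were the source of the few peaks on X, thinning autosomal peaks to its depth would leave about as many; 141 were expected at the corrected depth and 71.1 at the depth as counted, both above the upper Poisson bound of 64.8 for 49. That bound had been set in advance as counting against depth, but it left out how far autosomes differ, from 2.40 peaks per Mb on chromosome 3 to 7.03 on chromosome 11, and the rule was changed after this was seen. At the rate of chromosome 3 alone the expected numbers were 58.2 and 29.1, so depth and a true shortage of sites bound on X cannot be told apart.

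The palindrome with a 3-base spacer was weighed against a reading error of the search, since a 2-base site with 1 changed outer base can read as a 3-base spacer when shifted by 1 base. Sites whose spacer neither begins with C nor ends with G cannot arise from a site with 1 changed base. They still stood above random control regions (69 peaks of 316, odds ratio 9.92, 4.56 to 21.6) and GC-matched ones (3.69, 2.19 to 6.21). A lower bound of 5 had been set in advance as counting against the shift and was not reached. The rule was changed after the value was seen, because a shift of sites with 1 changed base allows no excess of such sites. The values argue against that shift as the whole source. A shifted 2-base site with more than 1 changed base can give such sites, so that source was left open. For the other sites a preference for the longer spacer would put T before CCCCNNGGGA more often in peaks, and T stood there in 31.4% of 1592 sites in peaks and 29.8% of 292 in control regions (odds ratio 1.08, 0.822 to 1.42), which is consistent with the shift. Whether EBF1 itself binds the sites left over was not tested.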

How the results depend on the processing

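The GC-matched test of spacer forms, the limit to well covered windows, the GC-corrected bins and 1 peak per distinct region were chosen after the data were seen, as was the choice to give single chromosomes, motifs and site forms as counts. The EBF site stayed above control regions under all 7 alternatives, with odds ratios from 15.6 to 131, and its relation to peak strength under both of its alternatives, including a difference of 19.9 percentage points (17.2 to 22.7) between the strongest and weakest groups where at least 90% of the window was covered. The count of enriched peaks moved to 4759 of the 4780 peaks with the highest deposited fold, where fewer were tested, and to 5501 with the first lane alone, at fewer reads. All reads gave an EBF1 share in peaks of 1.65%, 95 outside windows and 23.9% of peaks touched by a window. The peaks with the highest deposited fold took 1.08% of EBF1 reads and 0.278% of input reads, and 37.4% of them were touched. A ratio of at least 10 left 21 outside windows, and windows that cover at least 50% of a peak were found for 18.3%. Correction for GC content left 1 chromosome, X, more than 10% from the median. GC-matched control regions reversed FOXO (odds ratio 1.46), NF-kB (0.800), STAT5 (1.16) and the 1-base spacer (0.654), of which FOXO passed there; the cause was not tested. Of 28 values of single motifs under alternatives 23 kept direction and side of the threshold, of 22 site forms 19 did, and 19 of 20 chromosomes moved past their counting interval, by at most 5.80% with bins of 100 kb.

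No paired analysis of libraries was possible because there was 1 ChIP and 1 input library, and their lanes share nothing to pair. Peaks and control regions were matched in pairs, but the Fisher's exact tests treated them as separate groups. Alternatives planned for the position of peaks relative to genes and for gene lists were not run.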

Other observations

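All tests in this part were chosen after the data were seen. Among peaks with at least 90% of the window covered, 1570 held the exact EBF site, 3170 (42.0%) held only a site with 1 mismatch, and 2802 (37.2%) held neither. Median ChIP to input ratios were 3.47, 3.24 and 2.63 in turn, and 96.4%, 94.4% and 82.8% of the peaks passed the test against input. Of 12 forms with 1 mismatch, 9 were more frequent in peaks without an exact site than in control regions without one, while against GC-matched regions 7 were more frequent and 1 less. CCCCNNGGGA was found in 11.1% against 0.262% of control regions (odds ratio 47.6, 32.0 to 70.9) and TCTCNNGGGA in 9.57% against 0.514% (20.5, 15.3 to 27.4), followed by ACCCNNGGGA (11.4), GCCCNNGGGA (9.30), TCCGNNGGGA (9.24) and TCCTNNGGGA (4.30). The forms with a change at the next base stood near control levels, with TACCNNGGGA at 1.31 (0.652 to 2.62), TGCCNNGGGA at 1.49 (1.02 to 2.18, Fisher's exact test, adjusted p = 0.0524) and TTCCNNGGGA at 0.825 (0.527 to 1.29). Against GC-matched regions CCCCNNGGGA fell to 20.6, TCTCNNGGGA to 14.2 and TTCCNNGGGA to 0.606 (0.400 to 0.919, Fisher's exact test, adjusted p = 0.0296). TCACNNGGGA fell to 1.95 and still passed there, while TCGCNNGGGA (1.55) and TCCANNGGGA (1.34) no longer did. Next to exact sites the first outside base was read outward on each side, so C stands for C after GGGA or G before TCCC. In peaks this base was C in 36.0%, G in 32.2%, A in 18.3% and T in 13.4% of cases. In control regions, which were not matched on GC content here, the shares were 22.4%, 28.5%, 28.5% and 20.5%.

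Peaks with several sites were stronger. Those with 0, 1, 2 and 3 or more sites of at most 1 mismatch that did not overlap had median ratios of 2.63, 3.24, 3.69 and 4.77, and 10.5%, 22.5%, 37.5% and 60.2% of them were in the strongest of 5 equal groups of well covered peaks. Among the 4740 peaks with at least 1 site, Spearman's rho between holding more than 1 site and the excess of ChIP over input RPM was 0.162 (permutation test, p = 1e-05, the smallest possible), across peaks, which are not replicates. The excess was counted over whole listed regions, which differ in width. The arrays on chromosomes 18 and 17 are the strongest cases.

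Of the 2802 peaks without a site of at most 1 mismatch, 2794 had a GC-matched region, and sites of other factors were counted in these pairs at positions covered in both members. RUNX sites were found in 6.51% against 2.29% (odds ratio 2.97, 2.22 to 3.97), OCT sites in 0.966% against 0.322% (3.02, 1.42 to 6.43) and ETS sites in 2.43% against 1.22% (2.02, 1.34 to 3.07). MYC E-boxes, kept as a control, were found in 4.62% against 2.86% (1.64), and E-boxes in 28.9% against 23.1% (1.35). All of these passed two-sided Fisher's exact tests after adjustment over 14 motifs. In the same pairs the word CCCCAGAG (6.98% against 1.61%) led the search of all words, followed by ATGCACAC (5.23% against 0.787%). CCCCAGAG is part of TCCCCAGAGA, a form with 1 mismatch to the EBF site, and so is TCCCCAGA (5.26% against 1.07%). These peaks may therefore hold sites with more than 1 mismatch, which were not searched for. Over all covered positions of the window the repeat CACACACA was in 11.5% of the 2802 peaks, against 4.90% of peaks with the exact site and 4.73% of those with 1 mismatch. Peaks with the repeat and no site had a median ratio of 2.33, and 73.7% passed the test against input, compared with 2.70 and 83.9% without the repeat. When the 1570 peaks with the exact site were set against the 2802 without a site, also over all covered positions, 1 of 14 motifs differed, TTGGGAA of IKAROS, at 5.92% against 2.57% (odds ratio 2.39, adjusted p = 7.34e-07). That word shares TTGGGA with versions of the EBF site, and this overlap was not removed.

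Peaks were clustered along chromosomes. With 1 peak kept per distinct region (9344 of 9561), the nearest other peak was a median of 22.3 kb away, against 75.3 kb for the same number of control regions, and 33.5% of these peaks had another within 10 kb, against 9.80% of control regions. Counted over all 9561 peaks, chromosome 11 held 7.03 peaks per Mb and chromosome 19 held 5.86. No test was made of these values.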
